A study of Homo sapiens with 6 samples.

How the data were processed

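RNA sequencing counts from 6 libraries of LN229 cells, an established human glioblastoma line, were analysed: 3 libraries labelled as overexpressing HSD52, a long non-coding RNA gene, and 3 labelled as wild type, called control here. The labels do not say whether the control cells carried an empty vector, and they do not say whether the replicates came from separate cultures. The p-values therefore measure the spread between these libraries, which may be partly technical. Per the labels' protocols, total RNA was extracted with TRIzol, messenger RNA was selected on poly-T beads and fragmented, cDNA was primed with random hexamers, and the libraries were sequenced on an Illumina NovaSeq instrument. The protocol describes a second strand made with unmodified nucleotides, and no strand setting is given in the sources used here. Reads from overlapping and antisense genes could not be told apart, so the values of genes that overlap others are uncertain.

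The deposited values were raw read counts per gene, whole numbers with no normalization. Per the submitters' processing notes, bases were called with CASAVA, reads were aligned with HISAT2 2.0.5 to the hg38 build, and counts were made with featureCounts 1.5.0-p3. The annotation release and read filters are not given in the sources used here. Gene symbols, biotypes and coordinates (hg38) were taken as the deposited table gives them. The table held 58735 genes, of which 32917 had at least 1 count. Library totals ranged from 17777157 to 18917790 counts. At this depth 1 CPM corresponds to about 18 counts in a library. Intervals on count ratios are exact binomial 95% intervals on the summed counts of each group and cover counting error only, since the reads carried no molecular identifiers.

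Low-count genes were removed with filterByExpr, which left 16322 genes. Counts were scaled by TMM, and genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3, robust fit, 2-sided) on a design of group alone, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A second count added the requirement of a fold of at least 2. CPM values are TMM-scaled, and they are given as mean ± SD over 3 libraries per group. Log2 fold changes are HSD52_OE over control, with the standard error after ±. The replicate numbers in the labels were not stated to pair libraries, so the test had no replicate block.

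Before the data were examined, 42 gene lists were fixed, covering pathways, glioma cell states, markers of other cell types and signs of RNA quality. The 40 lists with at least 5 tested members were tested with camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and p-values were adjusted over the lists. Camera was repeated with a correlation estimated for each list. With 6 libraries this estimate is imprecise and the repeat has little power, so a list that fails it is undecided. Genes whose start lay within 1 Mb of the start of HSD52 formed a further set. Shares of changed genes by biotype were compared with Fisher's exact test, in which genes are treated as independent although they are not. Library measures were compared with exact 2-sided permutation tests, which cannot go below p = 0.1 for 3 libraries against 3.

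The rule for the genes named was also fixed beforehand. It took HSD52, the 10 protein-coding genes with the highest and the 10 with the lowest log2 fold change among those past the threshold, with a mean of at least 2 CPM and no overlap between the groups, and the 5 genes with the smallest p in each direction. It added the 3 long non-coding RNAs at either end under the same filters, the 4 members with the smallest p of each list that passed or had at least 3 changed members, and the neighbours of HSD52 past the threshold over that set. Other genes named were chosen after their values were seen, as members of blocks of adjacent genes or of gene families.

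The steps were tested on counts simulated from the mean and spread of each gene in the HSD52_OE against control comparison. Of the 16005 genes tested, a small part had known changes, far fewer than were called in the data. All of these were drawn from genes with higher counts, so recovery of changes in low-count genes was not measured. The test recovered 88.1% of genes changed 1.5-fold, 97.0% of those changed 2-fold and 100% of those changed 4-fold, all with the right sign. Of its calls, 9.52% were false, against a nominal 5%. For the lists, the shifted list was found and 0 of the other lists were called. Each gene was simulated independently and with the same spread in both groups, unlike the data. This result therefore does not show how often camera calls lists falsely when genes are correlated.

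The alternatives planned were RLE size factors, library totals alone, no filter beyond 1 count, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, protein-coding genes alone, an adjusted p of 0.01, glmTreat at a fold of 1.5, an estimated correlation, fry, and other windows. Correction for GC content and transcript length, a separate spread for each group, and removal of the genes in shifted chromosome blocks were added after seeing the data. GC content and length came from the longest GENCODE 29 transcript of each gene and were available for 99.96% of tested genes. Blocks were runs of 21 neighbouring genes with log2 CPM above 3 whose median passed a bound reached in 5% of 1000 shuffles of the gene order. Figures were drawn with matplotlib.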

Results

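The transcriptomes of LN229 glioblastoma cells with HSD52 overexpression were compared with those of LN229 cells labelled as wild type, with 3 libraries in each group. The comparison asked which genes differ when HSD52 is overexpressed. Total counts per library were 18250494, 18574853 and 18274253 in control replicates 1 to 3 and 17777157, 18491578 and 18917790 in HSD52_OE replicates 1 to 3. The means were 18366500 ± 180801 in the control group and 18395500 ± 576353 in the HSD52_OE group (SD, n = 3; exact permutation p = 1). The first principal component of log2 CPM carried 75.1% of the variance and separated the groups. Control libraries differed more from each other than HSD52_OE libraries did. The chi-square of counts per degree of freedom was 16.7 to 20.5 between control pairs and 2.32 to 3.76 between HSD52_OE pairs.

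HSD52 itself (ENSG00000224609, chromosome 1, 59131936 to 59296491, minus strand, annotated as a processed transcript) rose from 0.569 ± 0.148 CPM in control cells to 68.1 ± 1.22 CPM in HSD52_OE cells. Counts were 11, 7 and 12 in the control libraries and 1252, 1336 and 1327 in the HSD52_OE libraries. The log2 fold change was 6.89 ± 0.15 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.95e-14). The gene body overlaps LINC01358 and AC093424.1 in the table, and the counts do not separate transcripts of the endogenous locus from those of an introduced sequence.

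Expression changed widely in the HSD52_OE cells. Among the strongest increases was NLGN4X, a neuroligin that joins synapses, which rose from 0.533 ± 0.145 to 25.8 ± 0.595 CPM. TRAF1, an adaptor of TNF receptor signalling, rose from 15.2 ± 1.91 to 127 ± 11.4 CPM, and the nuclear receptor RORA from 1.61 ± 0.290 to 17.6 ± 1.39 CPM. Among the strongest decreases were the collagen gene COL3A1, from 16.3 ± 6.87 to 0.227 ± 0.0860 CPM, and the mechanically gated channel PIEZO2, from 14.2 ± 1.68 to 0.399 ± 0.0504 CPM. The transcription factor genes MYCN, CEBPD and CEBPB fell by 3.04 ± 0.13, by 2.94 ± 0.12 and by 1.86 ± 0.08 on the log2 scale.

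**Figure D1:**
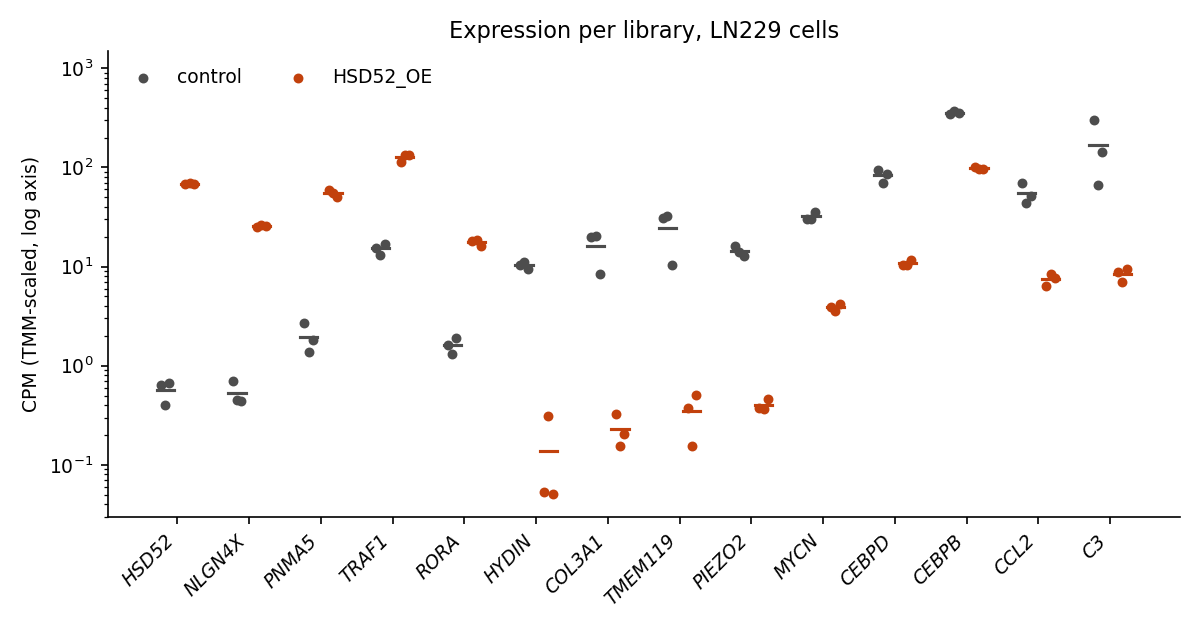
TMM-scaled CPM (log axis) of 14 named genes in each of the 6 libraries, with 3 points and a line at the mean per group. The groups do not overlap for any gene shown, with HSD52 at a mean of 68.1 CPM in HSD52_OE cells against 0.569 CPM in control cells, and CEBPB at 97.9 against 356 CPM.

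Further genes at the top of the ranking included FMR1NB, CALN1, PNMA5, VAT1L, SLC5A4, FOSB, SSX1 and FBLN5. From PNMA5 to FBLN5 the log2 fold changes ran from 4.81 to 3.45. FMR1NB had 1 count in the control libraries together against 277 in the HSD52_OE libraries, a ratio of 254 with a 95% counting interval of 45.2 to 10067. CALN1 had 2 against 468, a ratio of 215 (59.1 to 1777). FOSB, a component of AP-1, rose with a large spread, from 7.80 ± 6.21 to 146 ± 74.2 CPM (log2 fold change 4.22 ± 0.82, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.0145). Its adjusted p was 0.0544 without control replicate 1, 0.0510 without HSD52_OE replicate 1 and 0.0509 without HSD52_OE replicate 2 in the same edgeR test, and over all alternatives it ranged from 6.01e-07 to 0.0544. At the other end stood HYDIN, TMEM119, the metallothionein gene MT1E, the acute-phase gene SAA1, PLBD1, the glypican gene GPC4, the chemerin receptor gene CMKLR1, and C3, the central component of complement. Their log2 fold changes ran from -6.14 for HYDIN to -4.34 for C3. Control libraries varied in C3 (170 ± 119 CPM, against 8.34 ± 1.27 CPM in HSD52_OE), and the adjusted p of C3, 0.00951 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, was the largest of these 8. TGM2, a transglutaminase gene, fell from 52.0 ± 11.3 to 2.79 ± 0.574 CPM.

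Of the 16322 genes tested with edgeR's quasi-likelihood test, 4086 rose and 4173 fell, and 9205 had an unadjusted p under 0.05. At a fold of at least 2, 1707 rose and 570 fell. The groups did not overlap for 58.9% of genes, where chance gives 10%. Scaling by library totals alone raised the median log2 fold change of all genes by 0.12 and gave 5337 higher and 2933 lower genes, so the near balance of both directions rests on the composition scaling. A test against a fold of 1.5 called 1373 higher and 726 lower genes.

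Long non-coding RNAs rose far more often than they fell. Of 2208 tested, 959 rose and 103 fell, with a median log2 fold change of 0.60, while of 13155 protein-coding genes 2809 rose and 3959 fell, with a median of -0.06. The share that rose was 43.4% against 21.4% (odds ratio 2.83, 95% interval 2.57 to 3.11, Fisher's exact test p = 9.74e-100). Antisense genes (401 of 916 higher), sense intronic genes (58 of 117) and lincRNA genes (339 of 818) moved alike. The rise was not particular to long non-coding RNAs. Of 240 transcribed unprocessed pseudogenes 116 rose and 15 fell, and of 108 unprocessed pseudogenes 51 rose and 5 fell. Processed pseudogenes were balanced, with 71 higher and 78 lower of 423. The classes were not matched on expression level. Besides HSD52, the highest under the naming rule were AC025259.3 (log2 fold change 4.25 ± 0.50), which overlaps NR4A1, and AC105233.5 (3.89 ± 0.35). AP001972.5, LINC01505 and RAET1E-AS1 fell the most, by 2.39, by 1.77 and by 1.57 on the log2 scale. All 5 overlap other genes in the table and are uncertain without strand.

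**Figure D2:**
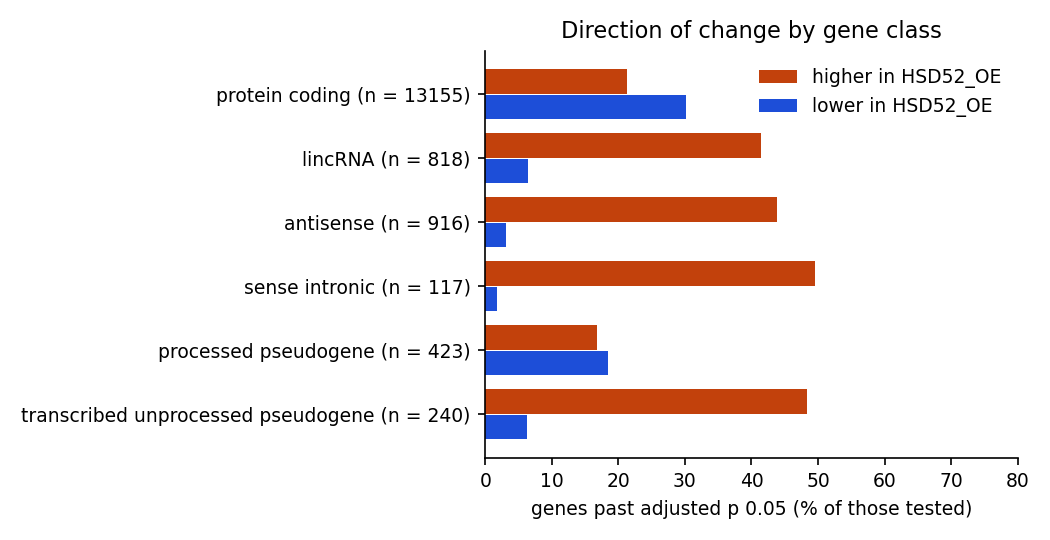
Percent of tested genes past an adjusted p of 0.05 (edgeR quasi-likelihood test) that were higher or lower in HSD52_OE, by biotype in the deposited table, with the number tested. More long non-coding genes were higher than lower, such as 43.8% against 3.06% of antisense genes, and protein-coding genes were 21.4% higher and 30.1% lower.

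The libraries differed in make-up in the same direction. HSD52_OE libraries held counts in 26558 ± 198 genes and control libraries in 23165 ± 350 genes. Long non-coding RNAs took 1.37% ± 0.0366 against 0.879% ± 0.0535 of counts (SD, n = 3), and sense intronic genes 0.0387% ± 0.00189 against 0.0210% ± 0.00143. Each of these 3 measures separated the groups, with an exact permutation p = 0.1, the smallest that the design allows, and a Benjamini-Hochberg value of 0.143 over 10 measures. Mitochondrial genes took 3.45% ± 0.107 against 2.99% ± 0.372 (exact permutation p = 0.2). Of 11 nuclear-retained and small-RNA host transcripts, a list that varies with RNA extraction, 7 rose and 0 fell over all genes and adjusted over the list alone. They included MALAT1, from 62.9 ± 13.2 to 340 ± 76.7 CPM, NEAT1, from 97.6 ± 4.36 to 363 ± 54.8 CPM, and KCNQ1OT1, from 20.4 ± 6.70 to 69.2 ± 1.15 CPM, which is antisense to KCNQ1 and uncertain without strand. The list passed camera (Benjamini-Hochberg adjusted p = 0.00581), but not with an estimated correlation (adjusted p = 0.713).

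Cell cycle genes moved in opposite directions by phase. Of 40 G2/M and mitosis genes, 34 rose and 2 fell, and adjusted over the list alone 35 rose and 2 fell (median log2 fold change 0.48). HMMR, a spindle protein gene, rose by 1.15 ± 0.09, KIF23, a cytokinesis motor, by 0.75 ± 0.08, CKAP2 by 0.89 ± 0.10, and NDC80, of the kinetochore, by 0.82 ± 0.09 on the log2 scale. Of 40 G1/S and replication genes, 2 rose and 24 fell by both adjustments (median -0.29). MCM6, of the replicative helicase, fell from 247 ± 4.15 to 151 ± 3.02 CPM, and the licensing factor CDT1, the transcription factor E2F1 and the histone mRNA-binding SLBP fell by 0.86, by 0.87 and by 0.76 on the log2 scale. Of 27 p53 targets, 12 rose and 2 fell by both adjustments, led by EDA2R, from 7.82 ± 1.25 to 32.5 ± 1.70 CPM, PERP, SESN1 and FBXW7. Camera passed the mitosis list (adjusted p = 5.17e-07), the replication list (0.000183) and the p53 list (0.0247) over 40 lists with Benjamini-Hochberg adjustment. With an estimated correlation the adjusted p were 0.650, 0.650 and 0.689, and the p53 list also had 0.0501 without control replicate 2 and 0.0838 with no low-count filter. Over its other alternatives the camera adjusted p of the p53 list went down to 0.00157.

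Inflammatory genes fell. Of 25 NF-kB targets and mediators, 1 rose and 19 fell by both adjustments, with a median log2 fold change of -1.11. The chemokine genes CCL2 and CXCL8 fell from 54.9 ± 13.5 to 7.45 ± 1.02 CPM and from 56.3 ± 12.4 to 13.7 ± 1.61 CPM, and the co-regulator BCL3 from 125 ± 7.70 to 31.3 ± 2.86 CPM. TRAF1 was the member that rose. The list passed camera (Benjamini-Hochberg adjusted p = 4.17e-05), with an adjusted p = 0.650 under an estimated correlation.

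Lists of glycolysis, hypoxia, fatty acid synthesis and the respiratory chain held more genes lower than higher. Among all protein-coding genes 21.4% rose and 30.1% fell. Of 19 glycolytic genes 1 rose and 14 fell over all genes, and 1 rose and 16 fell adjusted over the list alone. PFKL, GPI and HK2 fell by 0.86, by 0.77 and by 0.72 on the log2 scale, and ALDOC fell by 1.69 on that scale. ALDOC and FASN lie in shifted blocks of chromosome 17 given later, and NDUFS7 in that of chromosome 19. Of 29 hypoxia targets 4 rose and 16 fell (18 adjusted over the list alone), such as NDRG1, from 247 ± 31.1 to 74.2 ± 2.17 CPM, DDIT4, AK4 and EGLN1, the oxygen-sensing prolyl hydroxylase. Of 17 fatty acid synthesis genes 2 rose and 10 fell (11 adjusted over the list alone), including the desaturase SCD5 and FASN, the fatty acid synthase. Of 41 nuclear respiratory chain genes 4 rose and 16 fell by both adjustments, COX5A, NDUFS7 and SDHA lower and NDUFB8 higher. Camera adjusted p over the lists (Benjamini-Hochberg) were 0.000383, 0.0167, 0.00796 and 0.0247 in this order, and 0.689, 0.689, 0.713 and 0.713 with an estimated correlation. With protein-coding genes alone the hypoxia list had 0.0556 and the respiratory chain list 0.183, and the latter had 0.0504 without control replicate 3, 0.0668 without HSD52_OE replicate 1 and 0.0855 with library totals. Their lowest adjusted p over the alternatives were 4.44e-05 and 8.68e-05, both with no low-count filter. Of 24 cholesterol synthesis genes 3 rose and 10 fell by both adjustments. That list did not pass (camera Benjamini-Hochberg adjusted p = 0.149), with 0.0478 without control replicate 3 and 0.00495 with no low-count filter.

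Stress lists held more genes lower than higher, and differences between these lists were not tested. Over all protein-coding genes, 21.4% rose and 30.1% fell. Of 16 heat shock genes 0 rose and 11 fell by both adjustments, with HSPA1A, HSPA1B, the small heat shock gene HSPB1 and the co-chaperone gene BAG3 at log2 fold changes of -1.15, -0.95, -0.85 and -0.65. HSPA1A and HSPA1B are near-identical copies and share reads. Of 28 NRF2 targets and ferroptosis genes 4 rose and 16 fell by both adjustments. The ferritin gene FTH1 fell from 948 ± 49.6 to 388 ± 26.3 CPM and NQO1 from 933 ± 48.5 to 470 ± 8.22 CPM, while SLC7A11, the cystine transporter gene, rose from 29.3 ± 4.56 to 60.7 ± 4.22 CPM. Of 20 unfolded protein response genes 2 rose and 6 fell (1 and 3 adjusted over the list alone), so the share that fell was near that of all protein-coding genes. Of 28 ATF4 targets 6 rose and 11 fell (13 adjusted over the list alone). The heat shock and NRF2 lists passed camera (Benjamini-Hochberg adjusted p = 0.000383 and 0.0171), with an adjusted p = 0.650 for each under an estimated correlation, and over its other alternatives the NRF2 list ranged from 0.000147 with no low-count filter to 0.0643 with protein-coding genes alone. The unfolded protein response and ATF4 lists did not pass (0.613 and 0.189), and the ATF4 list had 0.0453 without control replicate 3 and 0.00512 with no low-count filter.

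Some matrix and signalling lists held more genes lower than higher, where 21.4% of all protein-coding genes rose and 30.1% fell. Of 41 mesenchymal and matrix genes 6 rose and 18 fell (19 adjusted over the list alone). MMP2 fell by 1.29 ± 0.11, TWIST2 by 1.36 ± 0.11 and SNAI1 by 0.86 ± 0.08 on the log2 scale, and TAGLN rose by 2.56 ± 0.14. TWIST2 lies in the shifted block of chromosome 2 given later. Of 28 receptor tyrosine kinases and ligands of glioma 4 rose and 17 fell (18 adjusted over the list alone), among them EGFR, from 52.4 ± 6.04 to 25.4 ± 3.17 CPM, PDGFA, AXL and FGFR1. Of 18 WNT targets 2 rose and 12 fell by both adjustments, among them NKD2, FZD7, TCF7 and BMP4. Of 23 YAP/TEAD targets 1 rose and 15 fell (16 adjusted over the list alone), with AXL, PTPN14 and FOXF2 lower and NT5E higher. Fibroblast markers, fixed as a sign of other cells, also held more genes lower than higher. Of 10 tested, 2 rose and 8 fell by both adjustments, with LUM and THY1 lower and FBLN1 higher. The 14 fibroblast genes in the deposited counts summed to 220 ± 53.5 CPM in control and 87.4 ± 0.553 CPM in HSD52_OE cells. These lists share members with other lists. Shared were 4 of the fibroblast markers tested, 10 mesenchymal genes, 7 kinases and ligands and 3 YAP/TEAD targets. Of 20 protease genes 5 rose and 3 fell, and of 22 TGF-beta targets 6 rose and 8 fell, by both adjustments.

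Camera adjusted p (Benjamini-Hochberg) were 0.0490 for the mesenchymal list, 0.00581 for the kinases, 0.000580 for WNT, 0.00288 for YAP/TEAD and 0.0171 for the fibroblast markers, and 0.812, 0.689, 0.650, 0.689 and 0.689 with an estimated correlation. The protease and TGF-beta lists did not pass (0.733 and 0.664). The mesenchymal list also had 0.0704 under the strict low-count filter, 0.198 without control replicate 1, 0.159 with protein-coding genes alone, 0.113 after correction for GC content and length, 0.0702 without the genes in chromosome blocks, and 9.09e-05 with no low-count filter. In all, camera called 3 lists higher and 13 lower of 40, and none of the 16 kept its call with an estimated correlation. The lowest adjusted p of any list in that repeat was 0.650 (Benjamini-Hochberg), and with 6 libraries it has little power to decide. Several lists share members, so these calls are not independent of each other. Other splits of the 6 libraries called up to 19 lists. Those splits set 2 libraries of a group against 1 and so keep part of the group difference.

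**Figure D3:**
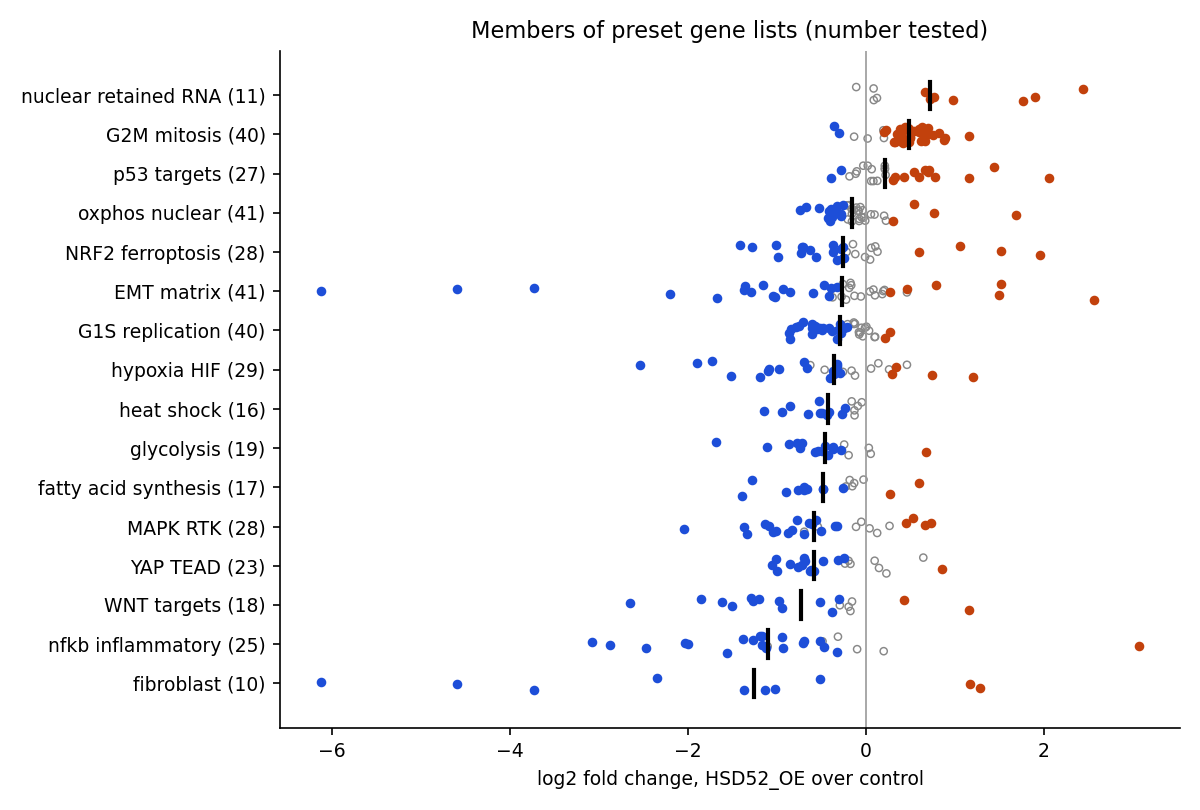
Log2 fold change of each tested member of the 16 lists that passed camera, with the number tested in brackets. Filled points passed an adjusted p of 0.05 (edgeR quasi-likelihood test), open points did not, and black lines mark list medians, from 0.72 for the nuclear-retained RNAs to -1.25 for the fibroblast markers.

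The other 24 lists tested did not pass camera, and several held strong changes in both directions. Among 37 interferon-stimulated genes 13 rose and 9 fell by both adjustments, with IFIT2, IFIT3 and TRIM22 higher and OAS3 lower (camera Benjamini-Hochberg adjusted p = 0.664). Among 29 immediate early genes 10 rose and 10 fell (11 adjusted over the list alone), with FOS at 143 ± 28.4 and 511 ± 121 CPM and FOSL1 at 235 ± 55.8 and 123 ± 11.7 CPM in control and HSD52_OE cells (0.888). The median of that list was -0.09, its mean was 0.30 and camera's direction was up, and the median was 0.03 with library totals and 0.01 without control replicate 3. Of 31 homologous recombination genes 12 rose and 4 fell by both adjustments, including BRCA2, RAD52 and CHEK2 among the higher (0.159, and 0.0434 with protein-coding genes alone), and of 15 end-joining genes 3 rose and 2 fell by both adjustments (0.659). Of 54 ribosomal protein genes 2 rose and 12 fell (2 and 10 adjusted over the list alone), with 0.127, and this list was called lower without control replicate 1 (camera Benjamini-Hochberg adjusted p = 0.000102, median -0.23 against -0.11), with no low-count filter (0.000431) and after correction for GC content and length (0.0274). Its median was 0.01 with library totals and -0.05 without control replicate 2.

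Markers of other cell types were fixed as a check of other cells in the cultures. Levels were summed over all list members in the deposited counts, tested or not. The sums in control and HSD52_OE cells were 46.0 ± 16.9 and 23.8 ± 2.78 CPM for microglia and macrophages and 183 ± 14.3 and 163 ± 2.80 CPM for endothelial cells. The sum of epithelial markers was 200.2 ± 5.79 CPM in HSD52_OE cells, 1.33 times that in control cells. The 15 lymphocyte genes in the deposited counts summed to 15.6 ± 0.648 and 32.3 ± 5.83 CPM. Only 2 of them were tested, and camera was not run on that list. Of the tested members, 1 of 6 microglial, 2 of 6 endothelial, 3 of 8 epithelial and 1 of 2 lymphocyte markers rose, and 1, 2, 2 and 0 fell, by both adjustments.

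Genes next to the HSD52 locus were examined for changes around it. MYSM1, a histone H2A deubiquitinase gene, rose from 44.8 ± 4.09 to 108 ± 6.53 CPM. Its lower coordinate lies 477 kb from that of HSD52. JUN rose from 145 ± 29.3 to 293 ± 63.3 CPM and FGGY, which begins just past HSD52, from 5.84 ± 0.371 to 7.81 ± 0.177 CPM. Of the 6 genes tested within 1 Mb, 3 rose and 0 fell over all genes, and adjusted over the list alone 3 rose and 1, CYP2J2, fell (log2 fold change -0.33 ± 0.14). FGGY lost its call without control replicates 1 and 3 and without each HSD52_OE replicate, with adjusted p from 0.0523 to 0.0881 (edgeR quasi-likelihood, Benjamini-Hochberg), and over all alternatives it ranged from 0.006 to 0.092. As a set the neighbours did not pass camera (median log2 fold change 0.31, p = 0.156, and p = 0.220 with an estimated correlation), but did with protein-coding genes alone (median 0.48, p = 0.0435). The median was 0.19 without control replicate 3, 0.46 without control replicate 2 and 0.48 without HSD52_OE replicate 1, and none of these fits passed camera.

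Changed genes were also grouped by position, which was noticed after the values were seen. On chromosome 17 (hg38), 42 of 46 protein-coding genes between 27456470 and 30637466 had a lower level in HSD52_OE cells, 36 of them past the threshold, with a median log2 fold change of -0.95. They included RAB34, from 132 ± 5.63 to 38.4 ± 2.08 CPM, MYO18A, FLOT2 and CPD. The next 20 expressed genes on either side had medians of 0.26 and -0.08, and NF1, just beyond, had 23.7 ± 2.59 and 24.1 ± 1.60 CPM. On the short arm of chromosome 12, 39 of 44 genes between 6970893 and 13219939 and 20 of 23 between 19129752 and 26833198 were higher, with medians of 0.67 and 0.58, SOX5 among the latter. Further blocks of lower genes lay at the end of chromosome 17, on chromosome 2 and at the start of chromosome 19, with medians from -0.50 to -0.58. The other blocks were less sharply bounded: on chromosome 12 the flanks had medians of 0.11 and 0.36 for the first block and 0.25 and 0.32 for the second, and flanks of the distal chromosome 17 blocks had -0.49, -0.41 and -0.32. The flanks on chromosomes 2 and 19 had -0.38 and -0.24. After correction for GC content and length, the chromosome 19 median went from -0.57 to -0.35. That of the last chromosome 17 block went from -0.56 to -0.33. Removing the 425 genes in the 7 blocks gave 3939 higher and 4008 lower genes in edgeR's quasi-likelihood test.

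**Figure D4:**
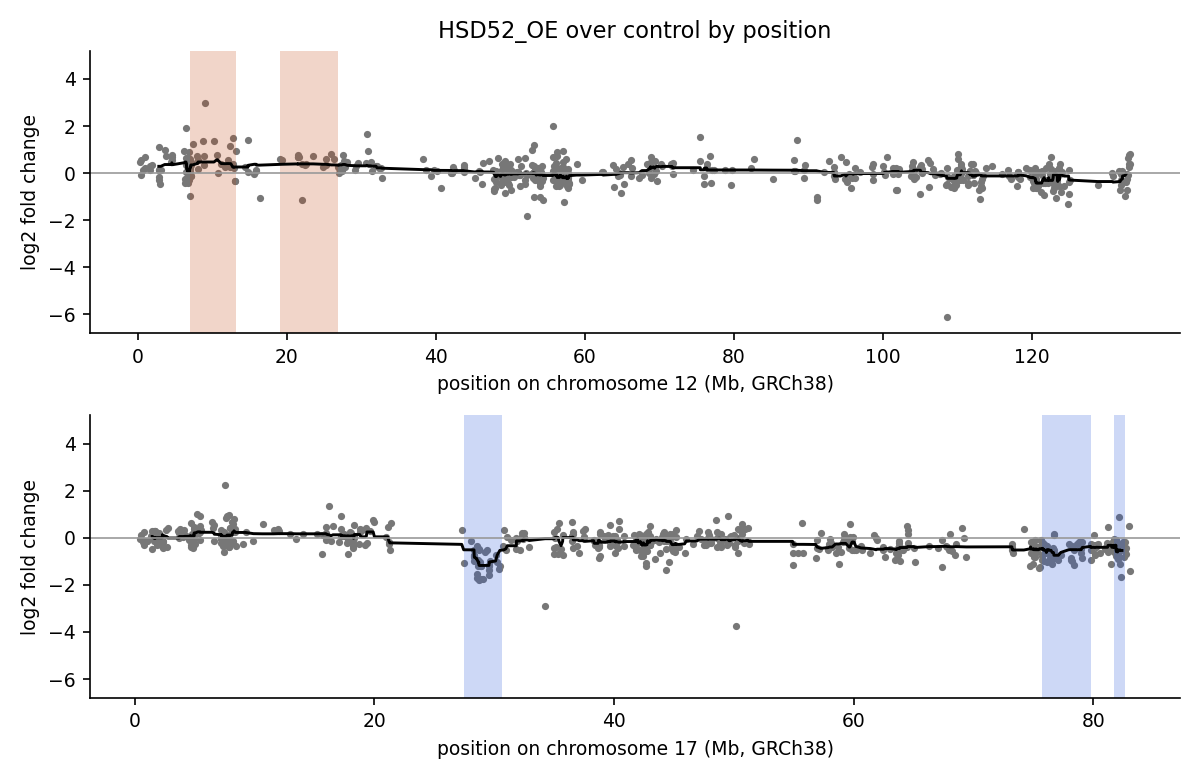
Log2 fold change (HSD52_OE over control) of protein-coding genes with a mean above 8 CPM by start position in Mb on chromosomes 12 and 17. The line is the running median of 21 genes, and shaded spans are the blocks of higher (orange) and lower (blue) genes, the deepest with a median of -0.95 on chromosome 17.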

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

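The corrections for GC content and length, the separate spread per group and the removal of block genes were chosen after seeing the data. HSD52 stayed past the threshold under all alternatives that tested it, with log2 fold changes from 6.68 to 7.01, and no result past its threshold changed direction. Of 2991 comparisons of 177 other named genes with an alternative, 2954 stayed on their side of the threshold, 28 lost it and 9 gained it. Leaving out each library gave 3373 to 4303 higher and 3313 to 4529 lower genes, 2 to 3 lists higher and 12 to 14 lower. The following counts moved by over 1.5 times. With glmTreat at a fold of 1.5, which asks for a larger change, 1373 genes were higher and 726 lower. With protein-coding genes alone, which tests fewer genes, 847 genes were at least 2-fold higher. Fry, which does not compare a list with other genes, called 6 lists higher. Camera called 20 lists lower with no low-count filter. In that setting the 32917 genes tested had a median log2 fold change of 0.23, against 0.01 in the main fit. Camera compares each list with the other genes, and whether this raised median made more lists lower was not tested. Camera with an estimated correlation called 0 lists higher and 0 lower (1 at an unadjusted p under 0.05), where fry called 6 and 17. The genes near HSD52 passed only with protein-coding genes alone (median 0.48). That setting leaves out a processed pseudogene, the lowest of the 6 neighbours (log2 fold change -0.63), and whether this alone gave the call was not tested. The 0.5 Mb window held too few tested genes for camera. The replicate numbers share correlations of 0.0307 to 0.0383 across groups, too low to pair the libraries, although all 6 libraries correlated best with their own number. A replicate block gave 4210 higher and 4226 lower genes. Added corrections gave 4244 higher and 4464 lower genes for GC content and length, and 3558 and 3988 with a spread per group. The odds ratio of long non-coding against protein-coding genes among those higher ranged from 2.20 to 3.17. Depth limits genes near the floor, such as FMR1NB, whose count ratio has an interval of 45.2 to 10067.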

Other observations

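Some gene families outside the fixed lists were picked after their values were seen, so their tests are not independent evidence. Of 27 X-linked cancer-testis antigen genes (MAGE, GAGE, PAGE, SSX, XAGE, CTAG and CT45), which are normally expressed in the germline, 13 rose, 1 fell and 13 did not pass in edgeR's quasi-likelihood test (median log2 fold change 0.89). PAGE5 rose by 2.32 ± 0.13 on the log2 scale and MAGEB2 from 34.0 ± 4.44 to 79.6 ± 1.80 CPM, while MAGEA3 was at 223 ± 19.2 and 205 ± 4.31 CPM. Near-identical copies in these families share reads. Of 33 HOX genes, which set position along the body axis, 4 rose, 16 fell and 13 did not pass, and HOXC13 fell from 20.2 ± 0.975 to 10.1 ± 0.514 CPM. Of 8 HOXB genes 4 rose, such as HOXB3, from 7.39 ± 0.544 to 12.5 ± 0.816 CPM, and 1, HOXB9, fell, and a difference between clusters was not tested. Of 467 numbered zinc finger genes 147 rose, 53 fell and 267 did not pass. With camera over these 3 families the Benjamini-Hochberg adjusted p were 0.00417, 0.0354 and 0.00417, and 0.158, 0.280 and 0.158 with an estimated correlation.

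Smaller sets from the fixed lists also held strong changes. NOTCH3 fell from 17.7 ± 4.74 to 4.64 ± 0.381 CPM with 6 of 12 Notch genes (1 rose), and camera did not pass that list (Benjamini-Hochberg adjusted p = 0.159). Of 4 tested metallothionein genes, MT1E and MT2A fell, and camera was not run on so few. The TGF-beta targets ID2 and INHBA rose by 1.83 and by 1.42 on the log2 scale, while 8 of the 22 members tested fell and 6 rose (median -0.13, mean 0.05). The median was -0.05 without control replicate 2 and -0.01 with library totals. In the lists of this paragraph the counts adjusted over the list alone were the same.

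The tests of gene order, sequencing depth, dividing cells and of the part of the blocks that excludes distal chromosome 17 were chosen after the results were seen. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. Each of the other 9 splits sets 2 libraries of a group against 1. Part of the group difference stays in them, and the rest adds to the spread within each side and holds the calls down. Their low numbers of changed genes therefore follow from the design and are no support for the real split. The real split gave 8259 changed genes in edgeR's quasi-likelihood test, and the highest of the other 9 gave 0, with 48 to 162 at an unadjusted p under 0.05. At a fold of at least 2 the real split gave 2277 and the highest other 0, so 1 of 10 splits reached the real value in each case. For the lists called by camera, the real split gave 16 and the highest other 19, and 4 of 10 splits gave as many.

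Blocks of adjacent genes on chromosomes 12 and 17 shifted together in all 3 HSD52_OE libraries. The order of genes by chance was argued against for the first chromosome 12 block and the proximal chromosome 17 block, whose most extreme windows were matched in 0% of 1000 shuffles (the others passed only a bound of 0.545 that 5% of shuffles reach), and GC content or length was argued against for the chromosome 12 blocks and the proximal chromosome 17 block, which kept at least 0.724 of their medians after correction. Of the distal chromosome 17 blocks 1 kept 0.774 and the other 0.582, so this cause stays open for the latter. The test set first covered all 5 blocks of chromosomes 12 and 17 and could not decide, because of the block that kept 0.582. The narrower set was formed with the results known, so only the shares kept by its blocks count, not its passing as a set. When blocks were found on every other gene, 86.1% of the 194 left-out genes in those of chromosomes 12 and 17 lay on the block's side (22 of 25 and 25 of 36 on proximal chromosome 17), so a difference in copy number between the cultures is a candidate explanation. These blocks ended by 21757857 on chromosome 12 and left out the reported chromosome 2 block, others appeared on chromosomes 6 and 15, DNA was not measured, other regional mechanisms predict the same, and whether such a difference came with HSD52 or with the selection of cells cannot be separated in this design.

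Non-coding genes were higher in HSD52_OE. Genomic DNA as the whole cause was argued against, since the gain per kb in olfactory receptor genes was 0.00940 of that in sense intronic genes, although their few counts went from 42 to 136 (a ratio of 2.97 per kb, against 1.69), so a small part stays open. More unspliced RNA predicted a larger gain in non-coding genes overlapping an expressed coding gene. Their summed gain per kb was 0.559 times that of those overlapping no tested gene. Gene by gene the order was reversed. Of the former 552 of 1185 rose (median log2 fold change 0.69), and of the latter 353 of 874 (0.51). Abundant genes weigh most in a summed gain, and transcripts of the latter genes can be unspliced too. The test therefore cannot decide, and this cause stays open. Sequencing depth was argued against, as mean total counts differed by 0.158%. A larger nuclear share in the RNA extract and an effect of HSD52 were not tested and stay open.

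Mitosis genes were higher and replication genes lower. GC content or length was argued against, as the lists kept at least 0.858 of their medians after correction. A plain difference in the share of dividing cells would move both lists one way. It was argued against as the whole cause by the directions alone, which were known when the test was chosen. Of 40 mitosis genes 34 rose and 2 fell, and of 40 replication genes 2 rose and 24 fell. The medians differed by 0.76 (log2), where 95% of 10000 pairs of random lists matched on expression differed by at most 0.201. Random lists lack the correlation among cell cycle genes, so this bound may be too narrow. With an estimated correlation camera passed neither list (Benjamini-Hochberg adjusted p = 0.650 for each). A different spread of cells over the phases of the cycle, through culture density or HSD52, was not tested and stays open.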
